A study of Homo sapiens with 3 samples.

How the data were processed

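RNA was measured on 3 one-colour Affymetrix arrays, each from 1 sample of MCF-7 cells. MCF-7 is an established human breast cancer cell line that expresses the estrogen receptor. Per the labels, the cells had been transfected for 48 h with a control siRNA (siControl, 1 sample) or with 1 of 2 siRNAs against the long non-coding RNA TMPO-AS1 (siTMPO-AS1, 2 samples, here siRNA 1 and siRNA 2). Biotin-labelled cRNA was prepared from 150 ng of total RNA, per the labels' protocols. The sequences of the siRNAs were not given in the sources used here.

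The values deposited by the authors were log2 expression levels, 1 per probe set and array. They came from Affymetrix Expression Console with RMA, per the submitters' processing notes, and the software versions and genome build were not given in the sources used here. RMA subtracts background, gives all arrays the same distribution of probe intensities and summarises the probes of each set. A change in the total amount of mRNA per cell is therefore not visible in these values, and dim transcripts have compressed ratios. The base of the logarithm was read from the range of the values.

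The table held 138745 rows, of which 2995 were control probe sets and 135750 were transcript clusters. The platform annotation listed 37295 of these clusters. It gave 1 gene symbol for 36176 rows and several genes for 1119, which were not used; 98455 clusters were not listed and stayed unnamed. Entrez identifiers of 25516 one-gene rows matched the RefSeq annotation of GRCh38.p14, which was used only for names, gene types and neighbouring genes, and 0 symbols needed an update. The rows named 33616 genes. For the 1576 genes with more than 1 row, the row with the highest mean over the 3 arrays was taken. Genes with a mean below the 25th percentile (log2 level 3.37) were left out, which kept 25212 genes. All value columns were used (0 left out).

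The log2 ratio of a siRNA is its log2 level minus that of the siControl array. A value given with an SD is the mean of the 2 siRNAs' log2 ratios, and the SD is that between the 2 siRNAs. It holds no error of the control, which had 1 array. The labels put both siRNAs under the same target, so siTMPO-AS1 (2 arrays) was compared with siControl (1 array) by limma (lmFit and eBayes, Benjamini-Hochberg adjustment over all genes kept, threshold 0.05). This fit has 1 residual degree of freedom, the difference between the siRNAs, and assumes that the lone control array varies like the siTMPO-AS1 arrays. The labels do not say whether the samples came from separate cultures, so the p-values measure only the spread between these samples, which mixes the siRNAs' own effects with array noise.

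Beside the test, genes were described by size: at least 1.5-fold apart from the control in the same direction with both siRNAs. Both ratios share the control array, so they go together without any effect. The count, the correlation and the covariance of the ratios were therefore set beside 100 simulations of 3 unchanged arrays. Their noise was drawn, within 20 bins of level, from the difference between the siRNA arrays, which holds real differences between the siRNAs as well as noise. With 1 control array the controls could not be split.

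Gene lists (25) were fixed before the data were examined, as were the groups, the tests, the naming rule and the alternatives, except 2 alternatives added later. List symbols were brought to current ones through RefSeq synonyms. Each list was tested with limma's camera with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were the alternatives. For each siRNA alone, the list's median log2 ratio was placed among 10000 random lists of the same size matched on mean level, which carry the same control array. The limma p-values of the members were also adjusted over the list alone.

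Named genes followed a rule. TMPO-AS1, TMPO and ESR1 were always named. The 12 genes higher and the 12 lower with the largest smaller ratio of the 2 siRNAs were named, as were up to 4 members per list by the same measure and the 5 genes in each direction that differed most between the siRNAs. Among the genes higher with both, 1 gene on the Y chromosome came up by rank and was left out. Genes named outside the rule are said to be so.

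The alternatives were no filter on dim genes, a filter at the median level, the mean over all rows of a gene, centring of arrays on their median, quantile normalization of the gene values, all rows whether named or not, and each siRNA left out in turn. Others were limma with trend or robust, an adjusted p threshold of 0.1, fold thresholds of 1.25 and 2, Spearman's rho, and list means. Cyclic loess between arrays and a restriction to protein-coding genes were added after seeing the data. The code was tested on simulated data with 200 changed genes among 25212: limma called 0 of them, with 50 genes each changed by a log2 of 1, 2, 3 and 4. The size rule recovered 34, 47, 49 and 50 of 50 at those sizes. Tools were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

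Signal quality was read from the control probe sets. The median of the 2197 positive control exons was 13.7 on the siControl array, 13.2 with siRNA 1 and 13.7 with siRNA 2. The 612 negative control introns had medians of 4.21, 4.15 and 4.01 in the same order. The 8 labelling and hybridisation spikes had medians of 9.22, 9.00 and 8.85. Among them the thr spike was lower with both siRNAs (9.16, 6.97 and 7.32), while the dap spike read 8.67, 8.88 and 8.16. The cause was not tested. Across the transcript clusters, Pearson's r was 0.967 between siControl and siRNA 1, 0.978 between siControl and siRNA 2, and 0.969 between the siRNAs (across transcripts, which are not independent replicates). The number of arrays limits the precision of every value.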

Results

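Transcript levels were profiled in MCF-7 cells, an estrogen receptor positive human breast cancer line, 48 h after transfection with siRNA. There were 3 arrays: 1 of cells given a control siRNA and 2 of cells given different siRNAs against TMPO-AS1, a long non-coding RNA whose gene overlaps that of the protein-coding gene TMPO. After filtering, 25212 named genes were compared on the log2 scale of the deposited RMA values. The median log2 ratio of all genes was -0.01 with siRNA 1 and 0.00 with siRNA 2.

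The targeted transcript was too close to background for the size of its knockdown to be measured. TMPO-AS1 had log2 levels of 4.95 on the siControl array, 3.68 with siRNA 1 and 4.20 with siRNA 2, so its values were lower with both. Background reached the same range: 33.8% of the negative control introns were at or above it on the siControl array, 63.2% with siRNA 1 and 44.3% with siRNA 2. TMPO, which encodes the nuclear lamina-associated proteins thymopoietin, was bright in the control (log2 level 14.87) and lower by a log2 ratio of -2.42 ± 0.26 (SD, n = 2). ESR1, which encodes estrogen receptor alpha, was 1.72-fold lower with siRNA 1 and 9.10-fold lower with siRNA 2 (-1.98 ± 1.70, SD, n = 2). The spread of ESR1 between the siRNAs was nearly as large as its mean ratio. None of these 3 genes passed limma's test.

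**Figure D1:**
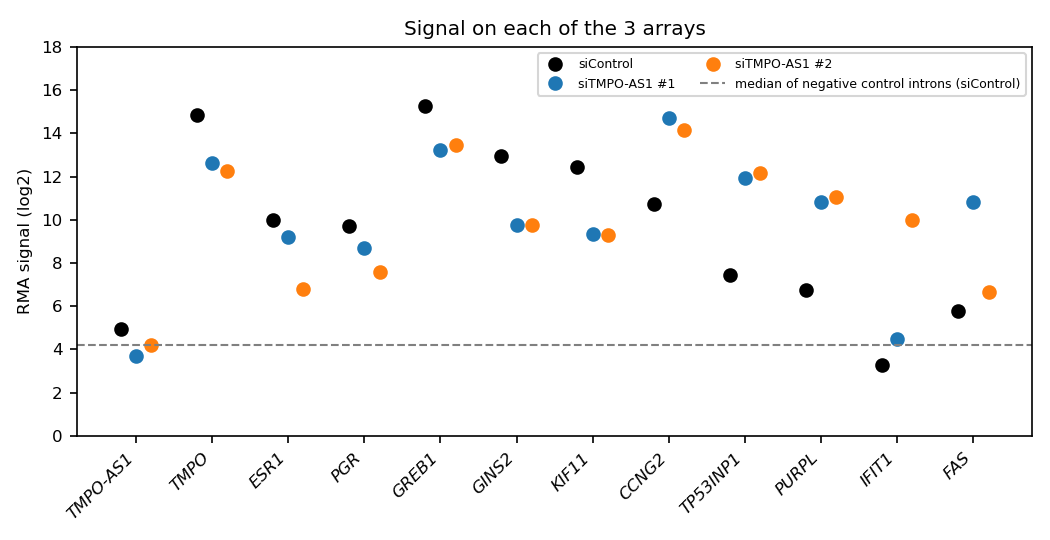
RMA log2 signal (vertical axis) of 12 genes on the 3 arrays, 1 point per array: siControl in black, siRNA 1 in blue and siRNA 2 in orange. The dashed line is the median of the negative control introns on the siControl array (4.21), near which TMPO-AS1 lies (4.95 in the control), while TMPO stands at 14.87 in the control and at 12.63 and 12.27 with the siRNAs.

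The comparison of siTMPO-AS1 with siControl asked which transcripts differ when TMPO-AS1 is targeted. Genes of DNA replication, mitosis and histone production were lower with both siRNAs, as were many estrogen-induced genes, while several p53 target genes were higher. Among the genes most strongly lower with both were GINS2, a subunit of the replicative helicase (-3.17 ± 0.01, SD, n = 2), the mitotic kinesin KIF11 (-3.15 ± 0.03) and XRCC2, which acts in homologous recombination (-3.53 ± 0.33). Among the genes most strongly higher were TP53INP1, a p53-induced gene (4.61 ± 0.18), PNRC1, a nuclear receptor coregulator (4.39 ± 0.41), and CCNG2, an atypical cyclin (3.70 ± 0.38).

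The other genes lower with both siRNAs by the naming rule included 4 histone genes. H3C8 had a mean log2 ratio of -4.13 ± 1.15 (SD, n = 2), H3C15 -3.88 ± 1.15, the pseudogene H2AC10P -3.72 ± 0.46 and H2BC10 -3.41 ± 0.52. Histone genes are nearly identical to their paralogs, so the probes may not tell them apart. EGR3, an estrogen-induced transcription factor, had log2 levels of 9.55 in the control, 6.49 with siRNA 1 and 4.41 with siRNA 2, the last at background. The zinc finger gene CXXC5 stood at -3.52 ± 0.32 (SD, n = 2) and RRP1B, which encodes a nucleolar protein, at -3.35 ± 0.41. TGFBR1, a TGF-beta receptor, and the sigma-2 receptor gene TMEM97 had ratios of -3.34 ± 0.38 and -3.17 ± 0.08. On the higher side stood the cadherin gene CDH18 (5.24 ± 1.78), GPNMB, which encodes a transmembrane glycoprotein (4.72 ± 1.37), and the actin-binding gene LIMA1 (3.97 ± 0.68). The p53-regulated long non-coding RNA PURPL was higher by 4.21 ± 0.17 and the receptor gene EDA2R by 3.89 ± 0.67. LINC00458 (4.35 ± 1.26), CSMD3 (4.04 ± 0.47) and the kinase gene DYRK1B completed this group. DYRK1B had log2 levels of 5.03 in the control, which is near background, and 8.79 and 8.74 with the siRNAs. The identifier of its probe set marks it as unmapped, so the gene that it reads is less certain.

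No single gene passed the test. Limma called 0 of 25212 genes at an adjusted p under 0.05, with a lowest adjusted p of 0.99997, and 960 genes had an unadjusted p under 0.05, against a mean of 1350 (1236 to 1457) in 100 simulations of unchanged arrays. By size, 3609 genes were at least 1.5-fold apart from the control in the same direction with both siRNAs, 1532 higher and 2077 lower. The simulated unchanged arrays gave a mean of 5074 such genes (4887 to 5289), so the number does not exceed theirs. Their noise was drawn from the difference between the siRNAs, which holds real differences too, so they set no calibrated level of chance. Lists of the genes 1.5-fold apart with each siRNA would, if independent, share 667 genes higher and 880 lower. Part or all of the excess over that may come from the shared control array.

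The log2 ratios of the siRNAs correlated across genes with a Pearson's r of 0.432 and a covariance of 0.287, and 63.4% of genes had the same sign with both. Simulated unchanged arrays with 1 shared control gave an r of 0.481 to 0.514, a covariance of 0.399 and 66.7% with the same sign. All simulated arrays had the same noise, so this r and this share of equal signs follow from the design, whatever the noise size. The simulated covariance follows from the size of that noise. These simulated values therefore cannot tell whether the siRNAs had an effect in common. The genes are not independent replicates, and the simulated noise was taken from the siRNA difference, which includes real differences between the siRNAs. The SD of the log2 ratios was 0.92 with siRNA 1 and 0.72 with siRNA 2.

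**Figure D2:**
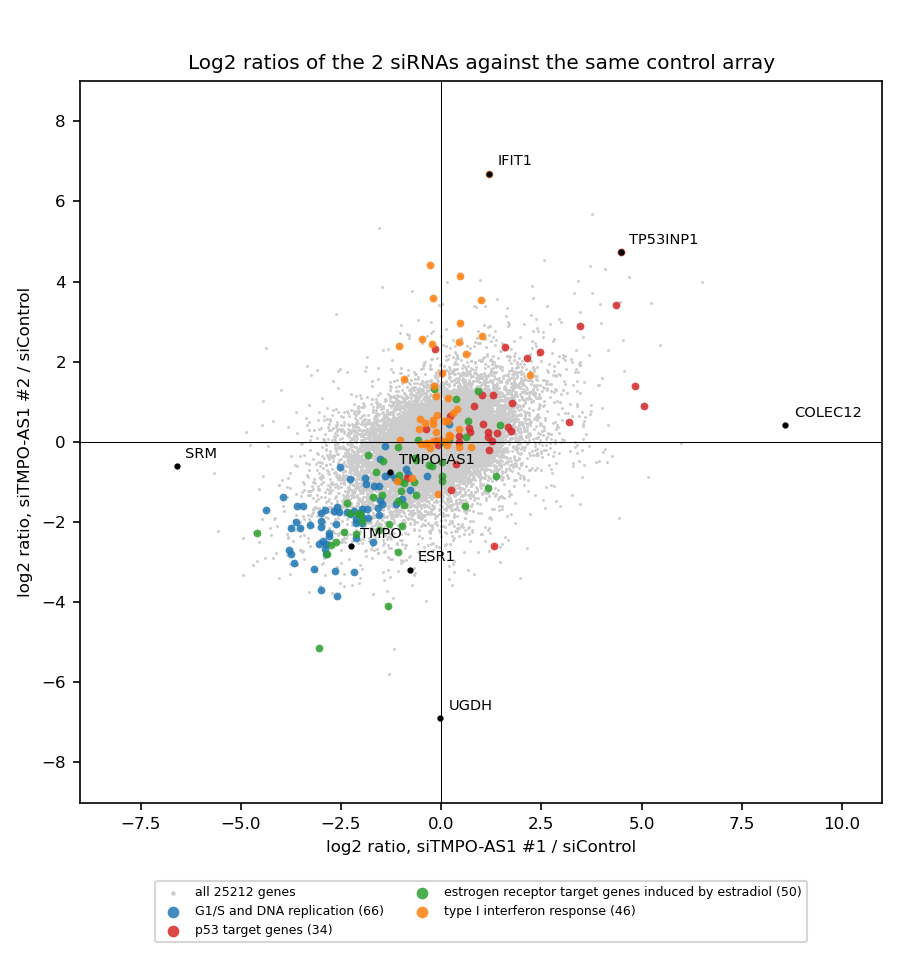
Log2 ratio of each of 25212 genes to siControl with siRNA 1 (horizontal axis) and siRNA 2 (vertical axis), 1 point per gene, with members of 4 gene lists in colour. G1/S and DNA replication genes lie at the lower left (list medians -2.28 and -1.77), p53 target genes mostly to the right (1.19 and 0.36), and interferon genes mainly upward (-0.09 and 0.54).

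Cell-cycle genes had the largest median shifts of the 25 lists. As lists, G1/S and DNA replication, G2/M and mitosis, and replication-dependent histones fell, with camera adjusted p-values of 4.30e-50, 8.93e-38 and 2.19e-27. Each of the 3 had an adjusted p = 0.684 with an estimated correlation, so none was called with that setting. Of 66 measured G1/S members, 62 were at least 1.5-fold lower with both siRNAs and 0 higher, where 10000 random lists matched on level held a median of 8 and at most 20 lower. Limma called 44 of these 66 genes when adjusted over the list alone and 0 when adjusted over all genes. The initiation factor gene CDC45 stood at -3.35 ± 0.47 (SD, n = 2) and DTL, part of a ubiquitin ligase that acts in S phase, at -3.35 ± 0.50. The replication gene MCM10 had a log2 level of 7.69 in the control and lay near background with the siRNAs (4.83 and 4.89). The G2/M list, with medians of -2.03 for siRNA 1 and -1.37 for siRNA 2, had 62 of 75 members at least 1.5-fold lower with both and 0 higher. They included CDCA3 (log2 levels 9.06 in the control, 4.66 near background with siRNA 1 and 6.17 with siRNA 2), the spindle checkpoint gene MAD2L1 (-3.12 ± 0.51) and CKS1B, a partner of cyclin-dependent kinases (-3.08 ± 0.52). Limma called 0 of the 75 when adjusted over the list alone. Of 43 histone genes, 35 were lower by this size and 0 higher (medians -2.33 and -1.51), among them H3C2 (-3.54 ± 0.92), H1-2 (-2.64 ± 0.12) and H2BC13 (log2 levels 8.18 in the control, 4.85 near background with siRNA 1 and 5.67 with siRNA 2), and 0 were called over the list alone.

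Genes that estradiol controls moved as groups in both directions. The list of estrogen receptor targets induced by estradiol fell, with medians of -1.01 with siRNA 1 and -1.10 with siRNA 2, and the list of genes repressed by estradiol in MCF-7 cells rose, with medians of 0.66 and 0.95. Their camera adjusted p-values were 1.46e-13 and 5.42e-06, and both had an adjusted p = 0.684 with an estimated correlation. Of 50 induced targets, 28 were at least 1.5-fold lower with both siRNAs and 1 was higher. After EGR3, the members lowest with both were the small heat shock protein gene HSPB8 (-2.83 ± 0.04, SD, n = 2), RERG, a Ras-like growth inhibitor (-2.66 ± 0.11), and the scaffold gene PDZK1 (-2.57 ± 0.09). The classical targets PGR, the progesterone receptor gene, and GREB1 are outside the naming rule and were chosen after their values were seen: PGR stood at -1.54 ± 0.78 and GREB1 at -1.91 ± 0.17. Of 19 measured members of the repressed list, 8 were at least 1.5-fold higher with both and 1, CXXC5, was lower. Membership was fixed beforehand, and whether estradiol represses each member was not checked here. TP53INP1, PNRC1 and CCNG2 led the higher members. TP53INP1 is also in the p53 list, and CCNG2 in that of cyclin-dependent kinase inhibitors and quiescence genes. Adjusted over the list alone, limma called 0 of the 50 induced and 5 of the 19 repressed genes; over all genes it called 0.

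Target genes of p53 rose as a list, with medians of 1.19 with siRNA 1 and 0.36 with siRNA 2 and a camera adjusted p of 6.44e-10. The adjusted p was 0.684 with an estimated correlation. Of 34 members, 12 were at least 1.5-fold higher with both siRNAs and 1 was lower, and limma called 3 when adjusted over the list alone and 0 over all genes. Besides TP53INP1 and EDA2R, the stress gene SESN1 stood at 3.18 ± 0.40 (SD, n = 2) and the ceramidase gene ACER2 at 2.35 ± 0.15. The list of cyclin-dependent kinase inhibitors and quiescence genes was not called (adjusted p = 0.151). Of its 19 members, 5 were at least 1.5-fold higher with both and 2 lower, and 3 were called over the list alone. Besides CCNG2, YPEL3 (2.64 ± 0.13) and the retinoblastoma family gene RBL2 (2.38 ± 0.01) were higher. RBL1, a relative of RBL2, was lower (-1.89 ± 0.04).

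**Figure D3:**
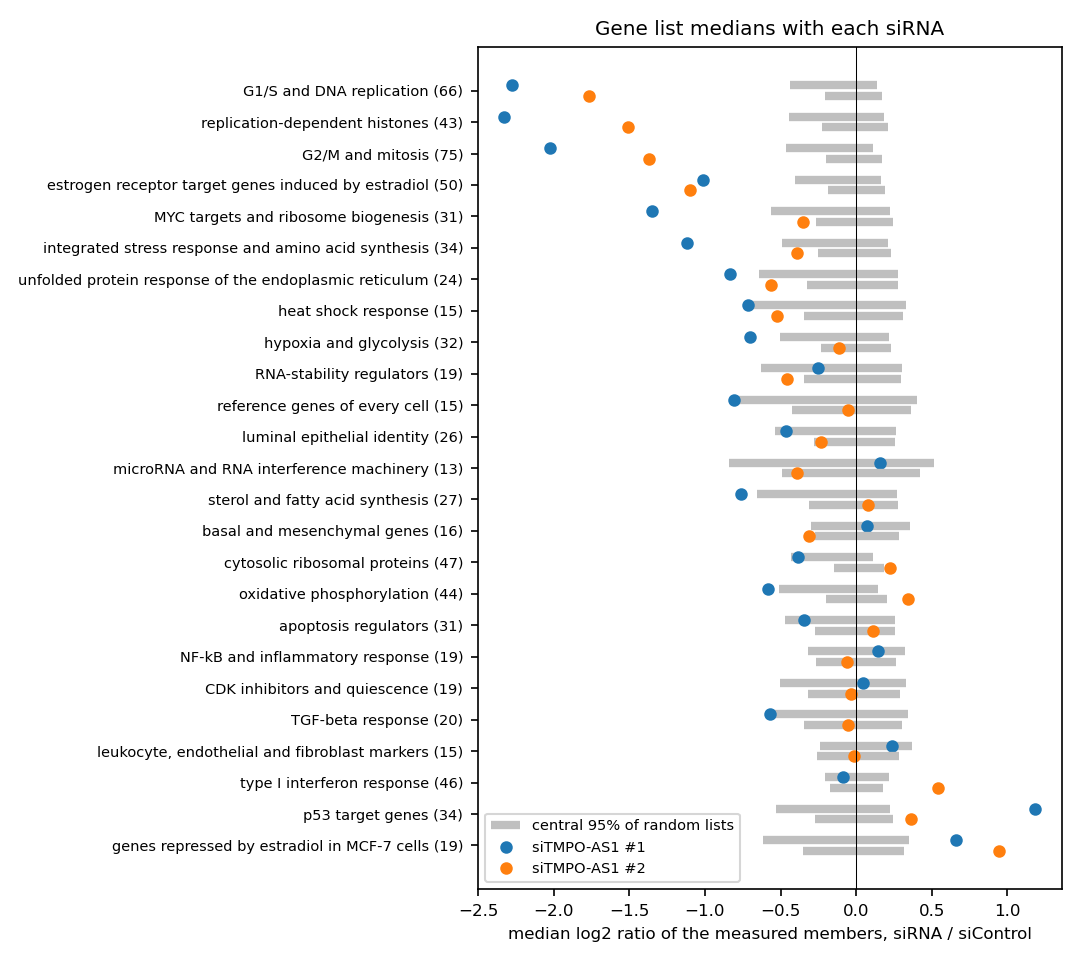
Median log2 ratio to siControl (horizontal axis) of the measured members of 25 gene lists with siRNA 1 (blue) and siRNA 2 (orange); grey bars are the central 95% of 10000 random lists matched on level, and the number of members is in parentheses. The G1/S list lies far below its bars with both siRNAs (-2.28 and -1.77), while oxidative phosphorylation lies on opposite sides of 0 (-0.58 and 0.34).

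Lists of growth and stress response genes fell against a background that was itself lower with siRNA 1. Reference genes had medians of -0.81 with siRNA 1 and -0.06 with siRNA 2, and positive control exons -0.44 and -0.09. Lists of MYC targets and ribosome biogenesis, the integrated stress response with amino acid synthesis, and the unfolded protein response fell, with camera adjusted p-values of 4.19e-07, 2.13e-06 and 5.42e-06. These were 0.723, 0.712 and 0.684 as adjusted p with an estimated correlation. The MYC list had medians of -1.35 with siRNA 1 and -0.35 with siRNA 2, and 11 of 31 members were at least 1.5-fold lower with both, where random lists held at most 11, and 0 were higher. They included the folate carrier gene SLC19A1 (-2.62 ± 0.33, SD, n = 2), the ribosome assembly gene GRWD1 (-2.52 ± 1.00) and MYC itself (-1.94 ± 0.58). The integrated stress response list (medians -1.12 and -0.39) had 11 of 34 members lower (at most 12 in random lists) and 1 higher, with the glutamine transporter gene SLC1A5 at -2.46 ± 0.27 and the cystine transporter gene SLC7A11 at -3.03 ± 1.59. CHAC1, a glutathione-degrading enzyme gene, had a log2 level of 7.76 in the control and lay near background with the siRNAs (4.86 and 4.94). The unfolded protein response list (medians -0.84 and -0.56) had 9 of 24 lower (at most 11 in random lists) and 0 higher, with the chaperone gene HSPA5 at -1.39 ± 0.0025 and XBP1, a transcription factor of this response, at -2.71 ± 1.97. No member of these 3 lists was called over its list alone, and the differences between the siRNAs were not tested.

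A further 3 lists fell: heat shock response, hypoxia and glycolysis, and RNA-stability regulators, with camera adjusted p-values of 0.000524, 0.00186 and 0.00720. Their values were 0.723, 0.684 and 0.712 as adjusted p with an estimated correlation. Among random lists, the heat shock median lay at percentile 1.955 with siRNA 1 and 0.47 with siRNA 2. The hypoxia median lay at percentiles 0.06 and 15.0 in the same order, so its fall rests on the siRNA 1 array. The RNA-stability median lay at percentiles 34.5 and 0.73, so its fall rests on the siRNA 2 array. Heat shock genes had medians of -0.71 with siRNA 1 and -0.53 with siRNA 2, 6 of 15 at least 1.5-fold lower with both (at most 7 in random lists) and 0 higher, with the cochaperone genes CHORDC1 (-1.37 ± 0.08, SD, n = 2) and STIP1 (-1.29 ± 0.36) lowest. Hypoxia and glycolysis genes had medians of -0.70 and -0.11, close to those of reference genes (-0.81 and -0.06), with 9 of 32 lower (at most 10 in random lists) and 1 higher, including the glucose transporter gene SLC2A1 (-1.66 ± 0.17) and the angiogenic factor gene VEGFA (-1.47 ± 0.02). RNA-stability regulators had medians of -0.25 and -0.46, 4 of 19 lower (at most 8 in random lists) and 1 higher, including the decapping enzyme gene DCP2 (-2.10 ± 1.09) and ZFP36L2, an RNA-binding decay factor (-2.11 ± 1.31). No member was called over its list alone.

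Interferon-stimulated genes were higher with siRNA 2. The type I interferon list rose, with a camera adjusted p of 0.00834, and the adjusted p was 0.767 with an estimated correlation. Its median log2 ratio was -0.09 with siRNA 1 (percentile 18.2 among random lists) and 0.54 with siRNA 2 (percentile 100), so the rise rests on the siRNA 2 array. With siRNA 2, 18 of 46 members were at least 2-fold higher, against at most 9 in the random lists, and 3 were with siRNA 1. IFIT1, an antiviral effector gene, had log2 levels of 3.29 on the siControl array, 4.49 with siRNA 1 and 9.98 with siRNA 2. The levels of IFIT3 were 3.80, 4.79 and 7.33, and those of IFIH1, a sensor of double-stranded RNA, 3.69, 4.71 and 6.33. Their control levels lie below the median of the negative control introns (4.21), so no fold is given. PARP9, at 7.43 in the control, had log2 ratios of 2.21 and 1.66. Limma called 0 members over the list alone.

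The luminal epithelial list had medians of -0.47 with siRNA 1 and -0.23 with siRNA 2, and its camera adjusted p of 0.0503 missed the threshold. Of its 26 members, 6 were at least 1.5-fold lower with both and 1 higher, with XBP1 lowest and MUC1 higher (0.91 ± 0.04, SD, n = 2). Basal and mesenchymal genes (0.07 and -0.31, adjusted p = 0.832) and markers of leukocytes, endothelium and fibroblasts (0.24 and -0.01, adjusted p = 0.222) were not called either. Also without a call by camera were NF-kB response (0.15 and -0.06, adjusted p = 0.918) and TGF-beta response (-0.57 and -0.05, 0.436). So were apoptosis regulators (-0.35 and 0.11, 0.477) and microRNA machinery (0.16 and -0.39, 0.992). Adjusted over the list alone, limma called 1 TGF-beta member and 0 members of the other 6 of these lists. For 3 lists the median of the members' mean ratios, the mean and the test did not share a sign. These were NF-kB (-0.06, -0.12, up), TGF-beta (0.09, -0.11, down) and the kinase inhibitor list (-0.05, 0.36, up).

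Transcripts that most cells express brightly were lower with siRNA 1 than with siRNA 2, a difference that was not tested. Positive control exons differed from the siControl array by a median of -0.44 with siRNA 1 and -0.09 with siRNA 2. Reference genes had list medians of -0.81 and -0.06 (camera adjusted p = 0.104). Oxidative phosphorylation genes had medians of -0.58 and 0.34 (adjusted p = 0.832), cytosolic ribosomal protein genes -0.38 and 0.22 (0.633) and sterol and fatty acid synthesis genes -0.76 and 0.08 (0.436). None of these 4 lists was called, with the lists adjusted together, and 0 of their members were called over the list alone.

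The siRNAs also differed from each other at single genes, with 1 array each and no test of the difference. With siRNA 1, COLEC12, a scavenger receptor gene, had a log2 level of 13.80, against 5.21 in the control, which is near background, and 5.62 with siRNA 2. UGDH, which makes UDP-glucuronic acid, was within 1.02-fold of the control with siRNA 1 and 118-fold lower with siRNA 2, and SRM, the spermidine synthase gene, was 96.7-fold lower with siRNA 1 and 1.52-fold lower with siRNA 2. ID3, which inhibits basic helix-loop-helix factors (log2 ratios -1.56 and 5.33), and the imprinted gene MEST (-4.37 and 2.34) were higher with siRNA 2, as was IFIT1. A further 4 genes had values near background, so their levels are given in the order siControl, siRNA 1 and siRNA 2. These were 7.12, 11.56 and 5.23 for the long non-coding RNA HECTD2-AS1 and 6.02, 11.18 and 5.15 for DRAIC, each near background with siRNA 2. The adenosine deaminase gene ADA2 stood at 3.29, 9.26 and 3.25, at background without siRNA 1. ID1, a relative of ID3, stood at 5.53, 2.89 and 8.72, near background on the siControl and siRNA 1 arrays. At the level of all genes, 10249 were at least 1.5-fold apart from the control with siRNA 1 and 7575 with siRNA 2.

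These comparisons rest on 1 control array, so a feature of that culture would appear in both ratios. With 1 residual degree of freedom, limma called 0 of 200 genes changed in simulated data, 50 of them by a log2 of 4, so its count of 0 says little about single genes. A gene's value was taken as near background where at least 20% of the negative control introns lay at or above it on that array, a limit set after the values were seen. Ratios of H2BC10, EDA2R, MUC1 and ID3 rest on 1 value that at least 10% of the introns reached, so their size is less certain.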

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

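The tests on TMPO and TMPO-AS1 were chosen before their results were seen; the tests on the cell-cycle lists, on the interferon genes and on unnamed rows were chosen after.

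The medians of the 3 cell-cycle lists lay outside the central 95% of random lists with both siRNAs, against 1 control array. No list was called with an estimated correlation (lowest adjusted p 0.684). Noise of that array that is independent between genes is argued against. The 10000 random lists matched on level, which carry the same array, had a lowest median of -0.53. That of G1/S and DNA replication was -2.09. Random lists cannot show noise that the genes of a list share. The weaker bright signal of the siRNA 1 array is argued against too: with siRNA 2 alone the G1/S median was -1.77, outside the central 95% of random lists (-0.21 to 0.17). A control culture that happened to grow faster cannot be told apart from an effect of the siRNAs, because there was 1 control array. Slower cycling after the knockdown, or after these siRNAs by another route, may explain the pattern and stays untested.

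The interferon genes moved apart between the siRNAs, as the difference of the list medians (siRNA 1 minus siRNA 2) was -0.63; the difference was not tested. Scatter of dim genes is argued against, since 18 members were at least 2-fold higher with siRNA 2 and no random list matched on level had over 9. Weaker bright signal with siRNA 1 is argued against for the rise with siRNA 2. That rise was measured against siControl, without the siRNA 1 array. The list median with siRNA 2 was 0.54, at percentile 100 among random lists matched on level. With siRNA 1 it was -0.09, at percentile 18.2. How much the weaker bright signal adds to the gap between the siRNAs is left open. The gap between the siRNAs was 0.56 after cyclic loess and 0.63 before. Cyclic loess did not remove that weaker signal, as reference genes still had medians of -0.62 with siRNA 1 and -0.09 with siRNA 2. A response of the cells to the siRNA 2 duplex itself may explain the interferon pattern. No array of an unrelated second siRNA was analysed here to test this.

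TMPO had lower values with both siRNAs, and its gene overlaps that of TMPO-AS1. TMPO lay at percentile 27.1 of the 140 other members of the G1/S and G2/M lists, whose mean log2 ratios had a median of -1.83 and a central 95% from -3.27 to -0.39. Its log2 ratio of -2.42 is thus in line with a shift shared with other cell-cycle genes, and a local effect on TMPO is not excluded. TMPO-AS1 was near background on all arrays, as at least 44.3% of the negative control introns were at or above it on each siTMPO-AS1 array. Its log2 ratio of -1.01 may therefore understate a knockdown or be scatter at background, and these values do not tell which.

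Besides interferon, 9 lists had medians on opposite sides of 0 with the siRNAs. In 4 of them a median also lay outside the central 95% of random lists with at least 1 siRNA, and the other 5 stayed inside it with both. For the 4 the difference (siRNA 1 minus siRNA 2) was not tested. It was 0.38 for basal and mesenchymal genes, -0.60 for cytosolic ribosomal proteins, -0.93 for oxidative phosphorylation and -0.84 for sterol and fatty acid synthesis. Among the 10 single genes named for their difference, ID3 and MEST had log2 ratios in opposite directions with the siRNAs, with untested differences (siRNA 1 minus siRNA 2) of -6.90 and -6.71. The computed differences were -5.83 for ID1, 6.33 for HECTD2-AS1, 6.03 for DRAIC and 6.01 for ADA2. In each of these 4 the lower value was at or near background, so the differences do not measure a size. ADA2 with siRNA 2 was within 1.5-fold of the control (log2 ratio -0.04, both at background), and the direction of ID1 with siRNA 1 is uncertain because both of its values were near background.

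Among the 98455 transcript clusters without a gene name, which entered only the alternative over all rows, 107 were at least 4-fold higher with both siRNAs and 38 lower. Among named genes 59 were higher and 143 lower by that size.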

How the results depend on the processing

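The choice of cyclic loess and of protein-coding genes as alternatives was made after seeing the data. Limma called 0 genes in every setting run. The number with an unadjusted p under 0.05 ran from 515 of 13184 protein-coding genes to 3961 of 101812 rows, named or not. The count of genes at least 1.5-fold apart with both siRNAs (3609 of 25212) was 1458 at 2-fold and 7114 at the lower fold threshold. Over all rows, named or not, the count was 11827 of 101812 rows, which is a smaller share. Of these rows 6574 were higher, against 1532 of 3609 in the main setting. With either siTMPO-AS1 replicate left out, 7575 to 10249 genes were 1.5-fold apart by the siRNA that remained, where agreement is no longer asked. The correlation of the ratios (0.432) was 0.387 as Spearman's rho and 0.450 over all rows; the cause was not tested. Of 13 lists called by camera, 0 were called with an estimated correlation (lowest adjusted p 0.684) and 0 with fry (lowest adjusted p 0.163); the estimate has 1 residual degree of freedom, and fry compares no list with other genes. The luminal list, not called in the main setting, was called in 3 of the alternatives and the cyclin-dependent kinase inhibitor list in 2. The interferon list's median (0.30) was -0.0898 without siTMPO-AS1 replicate 2, 0.54 without replicate 1 and 0.57 among genes at or above the median level. Without an siTMPO-AS1 array no residual degree of freedom is left, so limma's and camera's counts have no value there, and the control could not be left out. No paired analysis was possible because the 1 control carries no replicate number. Probe signal limits dim genes: TMPO-AS1 could not be measured well above the negative control introns.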

Other observations

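The gene families described here were chosen after their values were seen, by a search over 419 symbol stems and 4 gene types, and no test between conditions was run on them.

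Metallothionein genes, which bind zinc and copper and respond to metals and glucocorticoids, were lower with both siRNAs. Of the 17 measured genes and pseudogenes with the stem MT, 14 were at least 1.5-fold lower with both and 0 higher, with medians of -1.13 with siRNA 1 and -1.50 with siRNA 2. MT1E stood at -3.10 ± 0.30 (SD, n = 2), MT1G at -1.88 ± 0.76, MT2A at -1.33 ± 0.29 and MT1X at -1.21 ± 0.06. Metallothionein paralogs are nearly identical, so the probes of a member may also read its relatives, which was not tested. Of 22 beta-tubulin genes and pseudogenes, 11 were lower by this size and 0 higher, with medians of -1.47 and -0.56.

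Of 8 genes of Bardet-Biedl syndrome proteins, which carry cargo to primary cilia, 4 were at least 1.5-fold higher with both siRNAs and 0 lower, with medians of 1.27 and 0.80. BBS5 stood at 1.84 ± 0.22 (SD, n = 2), and BBS9 had log2 levels of 5.48 in the control, near background, 8.61 with siRNA 1 and 7.30 with siRNA 2. Of 22 bitter taste receptor genes and their relatives, 7 were higher by this size and 0 lower, with medians of 0.71 and 0.59. The median of each of these 4 families kept its sign with both siRNAs after centring, quantile normalization and cyclic loess.

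Some genes moved by at least 16-fold with 1 siRNA and stayed within 1.5-fold of the control with the other. With siRNA 1 alone 5 were lower: BAG2 (log2 ratio -4.76), CRABP2 (-4.20), CYB561 (-4.31), LRRC58 (-4.47) and MTPN (-4.87), all named after their values were seen. With siRNA 2 alone UGDH was lower, and the interferon-stimulated genes IFI6 (4.42) and OAS1 were higher. With siRNA 1 alone 7 were higher, COLEC12 and ADA2 among them. OAS1 had a log2 level of 4.49 on the siControl array, close to the negative control introns (median 4.21), and 8.64 with siRNA 2, so no ratio is given. CYB561 was dim with siRNA 1 (log2 level 5.41), so its ratio is less certain, and COLEC12 and ADA2 were near background in the control.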
